A study of Petunia x hybrida with 22 samples.

How the data were processed

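ChIP-seq of 4 histone marks in the petunia corolla at 7AM and 7PM was analysed from 16 lists of genomic intervals (islands), one of islands higher and one of islands lower at 7PM for each mark and replicate. Samples were grouped by mark and time, and numbered by replicate, from their labels. Replicates 1 and 2 were used for H3K4me3, H3K9ac and H3K27ac, and replicates 1 and 3 for H3K36me3, as labelled. Per the labels, tissue was crosslinked with 1% formaldehyde, nuclei were sonicated, chromatin was immunoprecipitated and NEBNext oligos were used to make libraries. The 6 input samples had no values in the lists and were not used here.

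Per the submitters' processing notes, cutadapt, Bowtie2 and SICER 1.1 were used. Their settings, the removal of duplicate reads, the use of the input samples in calling and the genome build are not given in the sources used here. Each deposited list has 13 columns without names, in the layout that SICER writes when it compares 2 libraries over merged islands. Island lengths are multiples of 200 bp without exception, which is the window step of the authors' calling. In each list the authors give the read counts of both libraries per island, the same counts as CPM (reads scaled to a library of 1000000 reads), the fold (a ratio) of one library to the other, and a p-value and FDR for each direction. The authors' deposited fold equals the ratio of the 2 counts after adding 1 read to each and scaling by the library totals to within a relative difference of 1e-06, which was checked on all 125384 islands. The authors' deposited lists hold only islands changed by at least 2.00-fold, with an FDR of at most 0.0097, and each list comes from one 7AM and one 7PM library rather than from pooled replicates. Islands that did not change are therefore missing from the lists, and shares of changed islands among all islands cannot be computed. The direction of each list comes from its label, because the columns carry no sample names. Library totals were taken from the quotient of count and CPM, which is the same for all islands of a library.

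The depth per library was 34316179 reads at 7AM and 51116862 at 7PM in H3K4me3 replicate 1, and 30199066 and 27700344 in replicate 2. It was 11507185 and 13031572 in H3K9ac replicate 1, 12998900 and 15757663 in replicate 2, 11366924 and 14140437 in H3K27ac replicate 1, 6721831 and 7945368 in replicate 2, 43918569 and 39485141 in H3K36me3 replicate 1, and 32431600 and 26643442 in replicate 3. In the shallowest library 3 reads correspond to 0.446 CPM, and in the deepest to 0.0587 CPM. In 267 islands one of the 2 libraries had 0 reads.

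Islands of both replicates of a mark that overlapped by 1 bp or more were merged into regions, and counts of islands within a region were summed per library. Regions that held both directions within a replicate were left out. Region folds are log2 values of 7PM over 7AM after adding 1 read to each count and scaling by library totals, given as the mean ± SD of the 2 replicate pairs. Because borders were set per pair, a region's counts in the 2 pairs can cover different lengths. Direction in one replicate was compared with direction in the other by two-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg method over 4 marks, and between marks over 6 pairs of marks. Single-replicate comparisons between marks numbered 24. The share with the same direction in unassociated lists was computed from the numbers of lower and higher regions on each side. Shares have exact (Clopper-Pearson) 95% intervals, and ratios of 2 counts have exact conditional binomial intervals.

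Regions listed in both replicates were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with robust dispersion on the deposited counts, each mark alone, with the replicate as a block and the library totals as library sizes, at an adjusted p under 0.05. The block was used because island borders belong to a pair. On data simulated with the H3K4me3 means, totals and dispersion, with 200 changed regions of 1866, the test recovered 84% of 2-fold and 100% of 4-fold changes and called 7 unchanged regions. For H3K36me3 (2567 regions) it recovered 92% and 100% and called 6 unchanged, for H3K27ac (4371 regions) 14% and 85% with 0 unchanged called, and for H3K9ac (2424 regions) 0% and 1% with 0 unchanged called. In these simulations most regions were unchanged and none was selected, whereas every real region had been listed as changed in both pairs. The dispersion also came from those selected regions, so the recovered shares do not carry over to the real test. The merging of islands, the density comparison, the border comparison and the shuffling of neighbours were also tested on simulated data. Alternatives were TMM and median-of-ratios scaling, DESeq2 1.42.0 with the block, no block, a filter of 50 reads, 50% reciprocal overlap, an FDR of 1e-05, a fold of 1.5, single replicates, and 1 region per scaffold.

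Regions are named by a rule set before the data were examined: for each mark and direction, the 5 regions with the largest fold, taking the smaller of the 2 replicate folds, with at least 50 reads in the higher library of each pair, plus the 5 loci per direction that changed in most marks, ties broken by the largest mean absolute log2 fold. Positions are 1-based on the scaffolds named in the lists. A gene annotation was not used here, so regions are not assigned to genes, and the planned tests of gene lists were not run. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.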

Results

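Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on corolla tissue of Petunia × hybrida cultivar Mitchell, a white-flowered garden petunia that releases its scent at night. Plants were kept in a greenhouse with 14 h of light and 10 h of dark, and tissue was taken at 7AM, soon after lights came on at 6AM, and at 7PM, shortly before lights went off at 8PM. Antibodies to 4 histone marks were used: H3K4me3, which sits around the start sites of active genes; H3K36me3, which lies over transcribed gene bodies; and the acetylation marks H3K9ac and H3K27ac of active promoters and enhancers. Each mark had 2 biological replicates at each time, which gives 16 ChIP libraries among 22 samples. The 6 input samples, 3 per time, were not used here. Library totals in the authors' counts were 27700344 to 51116862 reads for H3K4me3, 26643442 to 43918569 for H3K36me3, 11507185 to 15757663 for H3K9ac and 6721831 to 14140437 for H3K27ac. The question was which places of the genome carry more or less of each mark in the evening than in the morning.

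For every mark and replicate, the authors' deposited lists give the islands that were lower and those that were higher at 7PM than at 7AM. Together the authors' deposited lists held 125384 islands on 1608 scaffolds, of which 82219 (65.6%) were lower at 7PM and 43165 were higher. The H3K27ac lists leaned towards lower values in both replicates, with 13115 islands lower and 3227 higher in replicate 1 (80.3% lower, 95% exact binomial interval 79.6 to 80.9) and 11997 lower and 4977 higher in replicate 2 (70.7%, 70.0 to 71.4). The H3K9ac lists differed between replicates: 21714 islands were lower and 5699 higher in replicate 1 (79.2%, 78.7 to 79.7), against 5331 lower and 6415 higher in replicate 2 (45.4%, 44.5 to 46.3). For H3K4me3, 5143 islands were lower and 3277 higher in replicate 1 (61.1%, 60.03 to 62.1), while replicate 2 had 9569 lower and 9669 higher (49.7%, 49.0 to 50.4). For H3K36me3, 3702 islands were lower and 4021 higher in replicate 1 (47.9%, 46.8 to 49.1), while replicate 3 had 11648 lower and 5880 higher (66.5%, 65.7 to 67.2). The binomial intervals given here take islands or regions as independent draws. The count-ratio intervals cover the counting of reads only, and reads were not tagged as single molecules. Neither kind covers the variation between replicates. With only islands of at least 50 reads in the higher library, the share lower at 7PM was 65.6% in H3K4me3 replicate 2 and 58.5% in H3K36me3 replicate 1, so that both moved to the other side of an even split. It was 12.9% in H3K9ac replicate 2 and 90.4% in H3K36me3 replicate 3, which moved the 2 replicates of H3K9ac further apart (90.0% in replicate 1), and 68.3%, 88.9% and 71.2% in H3K4me3 replicate 1 and H3K27ac replicates 1 and 2.

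**Figure D1:**
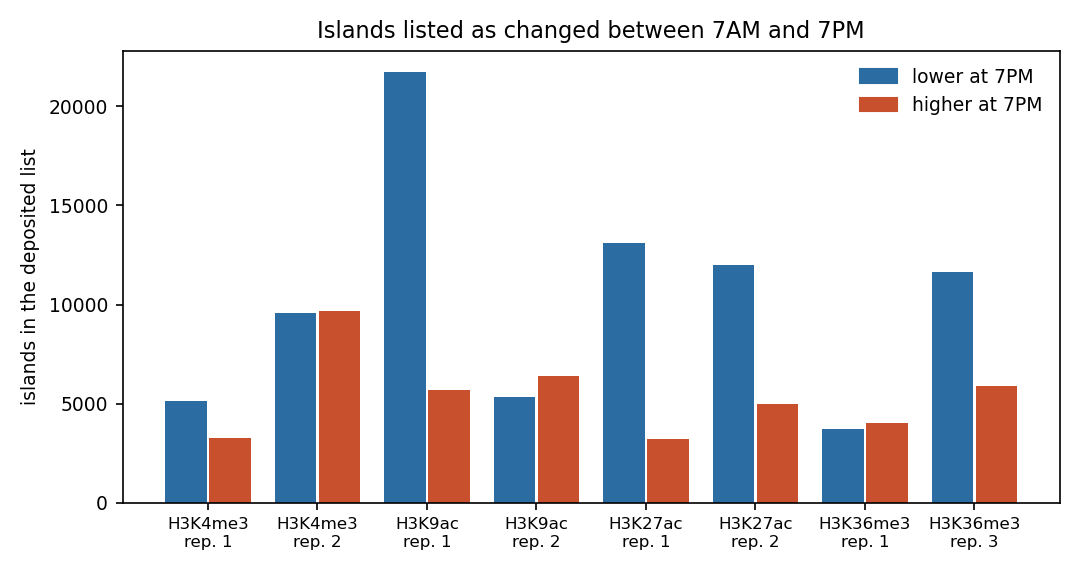
Bars show the number of islands in each deposited list (y axis, islands), one pair of bars per mark and replicate (x axis), blue for lower and orange for higher at 7PM. H3K9ac replicate 1 has the largest list, 21714 islands lower at 7PM, whereas replicate 2 of that mark has 5331.

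The islands were mostly short. The median length per list ran from 800 bp for higher islands of both H3K4me3 replicates and of H3K9ac replicate 1 to 3800 bp for lower islands of H3K36me3 replicate 3, whose longest member in the authors' deposited list covered 51.6 kb of Peaxi162Scf00089 (762001 to 813600; 5540 reads at 7AM and 1898 at 7PM). The longest falling H3K4me3 island was at the same place in both of its lists, on Peaxi162Scf00129 from 1566201, ending at 1580000 in replicate 1 and at 1579800 in replicate 2, with 2041 reads at 7AM and 1022 at 7PM in replicate 1 and 1212 and 330 in replicate 2. In the authors' deposited lists the fold of that island was 2.97 in replicate 1 and 3.36 in replicate 2. These 3 islands were chosen after their values were seen.

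Places listed in both replicates of a mark were then compared. Unassociated lists with the same balance would have the same direction at 81.1% of regions for H3K4me3 and 89.2% for H3K36me3. For H3K27ac and H3K9ac it would be 77.7% and 55.7%. For H3K4me3, 1843 of the 1866 regions listed in both replicates had the same direction (98.8%, 95% exact binomial interval 98.2 to 99.2). For H3K36me3 it was 2564 of 2567 (99.9%, 99.7 to 99.98), and for H3K27ac 4105 of 4371 (93.9%, 93.2 to 94.6). H3K9ac had the lowest value, 1756 of 2424 regions (72.4%, 70.6 to 74.2); of the 668 opposite regions, 576 were lower in replicate 1 and higher in replicate 2. The direction in one replicate was associated with the direction in the other for every mark, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 4 marks (adjusted p = 5.9e-226 for H3K4me3, 2.8e-98 for H3K9ac, 4.2e-236 for H3K36me3, and below 1e-300 for H3K27ac). Regions on one scaffold are not independent of each other; with 1 region per scaffold the shares were 99.1% for H3K4me3, 73.6% for H3K9ac, 96.7% for H3K27ac and 99.9% for H3K36me3. Among regions with at least 50 reads in the higher library of each pair, a filter chosen after seeing the data, the H3K9ac share was 87.6% (524 of 598).

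**Figure D2:**
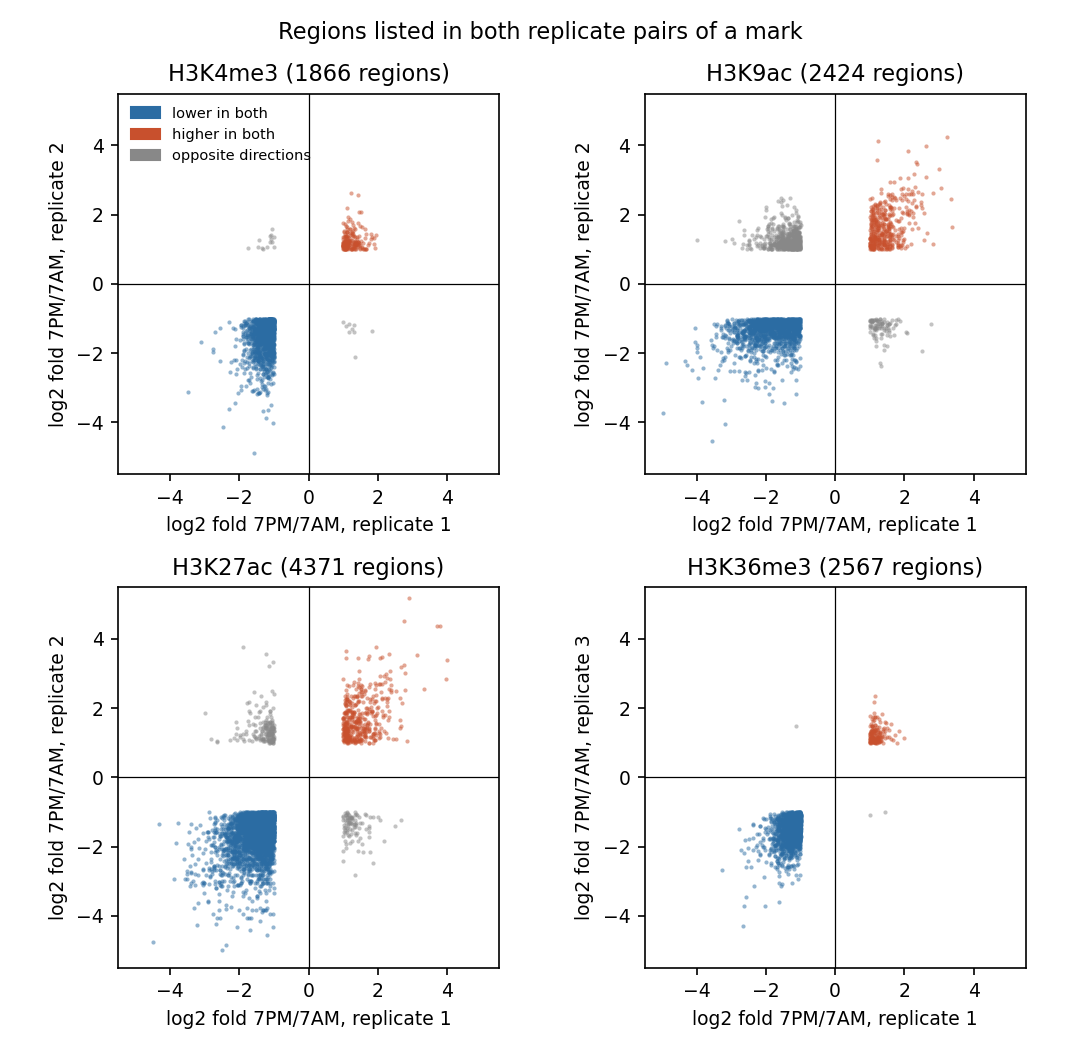
Each point is a region listed in both replicate pairs of a mark, with the log2 fold of 7PM over 7AM in one replicate (x axis) against the other (y axis); blue is lower in both, orange higher in both and grey opposite. The lists hold only changes of at least 2-fold, which leaves the centre empty, and H3K9ac has 668 grey points against 23 for H3K4me3, 266 for H3K27ac and 3 for H3K36me3.

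Among regions with one direction in both replicates, lower values at 7PM outnumbered higher ones for all 4 marks: 1657 against 186 for H3K4me3, 2418 against 146 for H3K36me3, 3680 against 425 for H3K27ac and 1352 against 404 for H3K9ac. Of the lower H3K36me3 islands of replicate 1, 65.6% were lower in replicate 3 as well, against 3.63% for the higher islands, and of those of replicate 3, 21.0% and 2.48% were listed likewise in replicate 1. The shares for H3K4me3 were 32.3% and 5.74% from replicate 1 and 17.6% and 1.94% from replicate 2, and for H3K27ac 29.1% and 13.6%, and 32.2% and 8.82%. For H3K9ac they were 6.47% of the lower and 7.63% of the higher islands of replicate 1, and 26.2% and 6.33% of those of replicate 2. No test of these shares was made, and they depend on the length of the other list.

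H3K4me3 fell at 1656 regions and rose at 186 of the 1866 tested (edgeR quasi-likelihood test with the replicate as a block, adjusted p under 0.05). Without the block edgeR called 16 lower and 0 higher (467 and 44 at an unadjusted p under 0.05), DESeq2 with the block called 1617 and 141, and 9 of the 10 regions named below no longer passed without the block. Over the regions lower in both replicates the median log2 fold was −1.32, and over the higher ones it was 1.22. The first named fall was on Peaxi162Scf00047 at 2205001 to 2206200, by −3.30 ± 0.24 (log2, SD, n = 2 replicate pairs), where reads went from 163 at 7AM to 21 at 7PM in replicate 1 and from 85 to 8 in replicate 2. H3K4me3 also fell on Peaxi162Scf00316 at 500801 to 503600 (−2.17 ± 0.027), on Peaxi162Scf00078 at 782201 to 784000 (−2.15 ± 0.078), on Peaxi162Scf00714 at 595401 to 597200 (−2.60 ± 0.78) and on Peaxi162Scf00091 at 1370201 to 1373400 (−2.17 ± 0.33). With scaling by library totals rises were smaller, and none of the 186 exceeded 4-fold in both replicates, but under TMM the edgeR log2 folds of the 5 named rises were 2.56 to 2.87 and those of the 5 named falls −0.85 to −2.24. The first named rise was on Peaxi162Scf00687 at 379401 to 381400 (1.35 ± 0.052). Reads there went from 13 at 7AM to 51 at 7PM in replicate 1 and from 31 to 76 in replicate 2. The others were on Peaxi162Scf00001 at 690001 to 692000 (1.34 ± 0.072), Peaxi162Scf00185 at 558601 to 560400 (1.496 ± 0.30; 15 to 57 reads and 25 to 77 reads), Peaxi162Scf00640 at 164601 to 165800 (1.26 ± 0.0042; 20 to 74 reads and 23 to 52 reads) and Peaxi162Scf00553 at 519001 to 521400 (1.36 ± 0.16; 119 to 424 reads and 131 to 335 reads). The level of these places over the input samples was not tested. The edgeR adjusted p of these 10 regions lay between 0.0026 and 0.0036. Rising regions had a median of 1.02 CPM (reads scaled to a library of 1000000) per kb over the 4 libraries, against 2.29 for falling regions.

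H3K36me3 fell at 2418 and rose at 146 of 2567 regions in the same test, which are all of the regions listed in one direction in both replicates. Falling regions had a median length of 2400 bp and a median log2 fold of −1.29, rising regions 1000 bp and 1.20. The mark fell on Peaxi162Scf00047 at 1238601 to 1239600 (log2 fold −2.52 ± 0.12, SD, n = 2 replicate pairs; 83 reads at 7AM and 13 at 7PM in replicate 1, 58 and 7 in replicate 3), on Peaxi162Scf00521 at 442001 to 443800 (−2.46 ± 0.065), on Peaxi162Scf00074 at 612401 to 613200 (−2.31 ± 0.11), on Peaxi162Scf00094 at 1167801 to 1168400 (−2.19 ± 0.073) and on Peaxi162Scf00050 at 1647201 to 1648400 (−2.86 ± 1.19). It rose on Peaxi162Scf00184 at 734201 to 735000 (1.28 ± 0.0017; 25 reads at 7AM and 56 at 7PM in replicate 1, 26 and 53 in replicate 3). The other named rises were on Peaxi162Scf00480 at 745601 to 746200 (1.30 ± 0.11), on Peaxi162Scf00141 at 467401 to 469400 (1.23 ± 0.063), on Peaxi162Scf00299 at 1065601 to 1066200 (1.25 ± 0.11) and on Peaxi162Scf00094 at 1335401 to 1338200 (1.25 ± 0.20). The edgeR adjusted p of these regions was at most 2.8e-08. Rising regions had a median of 1.22 CPM per kb over the 4 libraries, against 1.84 for falling regions.

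H3K27ac fell at 3638 and rose at 418 of 4371 regions, with median log2 folds of −1.47 over the regions lower in both replicates and 1.53 over the higher ones. The first named rise was on Peaxi162Scf00002 at 345401 to 351400, where reads went from 34 at 7AM to 605 at 7PM in replicate 1 (2.99 to 42.8 CPM) and from 19 to 486 in replicate 2 (2.83 to 61.2 CPM), a log2 fold of 4.08 ± 0.40 (SD, n = 2 replicate pairs). Further rises were on Peaxi162Scf00314 at 862801 to 865800 (4.05 ± 0.47), Peaxi162Scf00481 at 325001 to 327600 (3.70 ± 0.43) and Peaxi162Scf00740 at 114201 to 116400 (3.33 ± 0.30). On Peaxi162Scf00655 at 132601 to 134000 replicate 1 went from 13 to 129 reads, a ratio of 7.98 (95% counting interval 4.50 to 15.4), and replicate 2 from 1 to 84 reads, a ratio of 71.1 (12.4 to 2840). The first named fall was on Peaxi162Scf00092 at 1565601 to 1569600, from 473 to 25 reads in replicate 1 and from 183 to 7 in replicate 2, a log2 fold of −4.63 ± 0.18. H3K27ac also fell on Peaxi162Scf00408 at 236001 to 245600 (−3.54 ± 0.33), Peaxi162Scf00472 at 629001 to 632400 (−3.74 ± 0.73), Peaxi162Scf01517 at 103201 to 105400 (−3.41 ± 0.29) and Peaxi162Scf00439 at 672401 to 680800 (−3.20 ± 0.12). The edgeR adjusted p of these 10 regions lay between 0.0062 and 0.0067. In all, 226 falling and 41 rising regions changed over 4-fold in both replicates.

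For H3K9ac, 1352 regions were listed lower and 404 higher in both replicates, with median log2 folds of −1.58 and 1.51, but the edgeR test called 0 of 2424 regions at an adjusted p of 0.05. At an unadjusted p under 0.05 it gave 851 lower and 283 higher, and DESeq2 called 408 lower and 156 higher. Restricted to the 598 regions with at least 50 reads in the higher library of each pair, edgeR called 316 lower and 155 higher. The biological coefficient of variation in the edgeR fit was 0.47 for H3K9ac, against 0.098 for H3K4me3, 0.14 for H3K27ac and 0.091 for H3K36me3. The fits include regions with opposite directions in the 2 replicates, 668 for H3K9ac against 23, 266 and 3 in the same order. The value for H3K9ac therefore partly restates that disagreement. The named regions higher in both H3K9ac replicates were on Peaxi162Scf00825 at 229201 to 230600 (log2 fold 3.73 ± 0.71, SD, n = 2 replicate pairs; 7 to 84 reads and 6 to 159 reads), Peaxi162Scf00655 at 132601 to 134600 (3.15 ± 0.22), Peaxi162Scf00058 at 152201 to 153800 (2.91 ± 0.19), Peaxi162Scf00002 at 345601 to 351000 (3.31 ± 0.95) and Peaxi162Scf00061 at 1477001 to 1478000 (2.86 ± 0.33). Those lower in both were on Peaxi162Scf03779 at 87601 to 92400 (−3.10 ± 0.53; 314 to 31 reads and 174 to 31 reads), Peaxi162Scf00774 at 325001 to 326600 (−3.34 ± 0.89), Peaxi162Scf00481 at 487601 to 490200 (−2.57 ± 0.0033), Peaxi162Scf00439 at 672201 to 677200 (−2.65 ± 0.17) and Peaxi162Scf00188 at 669801 to 674200 (−2.93 ± 0.62). All 10 had an edgeR adjusted p of 0.105, and all 10 passed with DESeq2 and with the filter of 50 reads.

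The authors' threshold selected the regions before they were tested, so these p-values describe how closely the 2 pairs of a mark agree within an already changed set, not a survey of the whole genome. For H3K4me3, H3K36me3 and H3K27ac the calls nearly repeat the regions listed in one direction in both replicates, and add little to the lists. The split of calls was obtained with scaling by library totals. TMM normalization centres the selected regions near no change, which moved the log2 folds by a mean of 1.26 for H3K4me3, 1.28 for H3K36me3, 1.42 for H3K27ac and 0.94 for H3K9ac; median-of-ratios scaling moved them by 1.28, 1.29, 1.42 and 1.09. Under TMM the calls were 18 lower and 186 higher for H3K4me3 (8.82% lower, in place of 89.9%), 81 and 155 for H3K36me3 (34.3% in place of 94.3%), 66 and 419 for H3K27ac (13.6% in place of 89.7%) and 54 and 345 for H3K9ac (13.5%). Under median-of-ratios scaling they were 15 and 186, 57 and 150, 64 and 418, and 27 and 359 in the same order. Most tested regions fell, so centring them takes away most lower calls by construction, and the changed split does not show what it depends on. The falls of most regions are given relative to the library total. Both scalings move every fold upwards, so the counts of higher regions do not test whether rises depend on scaling. The 5 named falls of each of H3K4me3, H3K36me3 and H3K27ac still passed the test under both.

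Directions were next compared between marks, over regions with one direction in both replicates of each. The acetylation marks had one direction nearly throughout: H3K9ac and H3K27ac had the same direction at 769 of 770 shared regions (99.9%, 95% exact binomial interval 99.3 to 99.997), 624 lower and 145 higher (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over 6 pairs of marks, adjusted p = 4.0e-158). H3K4me3 and H3K36me3 were lower together at all 508 regions they shared, and no rising region was shared, so Fisher's exact test had nothing to compare (p = 1). An acetylation mark and a methylation mark shared fewer regions: 84 of 96 had the same direction for H3K4me3 and H3K9ac, 199 of 208 for H3K4me3 and H3K27ac, 47 of 59 for H3K9ac and H3K36me3 and 139 of 152 for H3K27ac and H3K36me3. Methylation was higher at 1 region in each of these 4 tables, so the exact p-values (0.135, 0.0481, 0.220 and 0.0921; 0.203, 0.144, 0.264 and 0.184 adjusted) were the smallest that the tables allow, and the test says nothing about association there.

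Single replicate pairs gave other values where H3K9ac replicate 2 took part. Since most lists lean to one direction, each share is given beside the one that unassociated lists with the same balance would have. H3K9ac replicate 1 had the direction of H3K4me3 replicate 1 at 97.6% of 1940 shared regions (94.6% unassociated) and of H3K36me3 replicate 3 at 96.2% of 3552 (88.8%). H3K9ac replicate 2 had the direction of H3K4me3 at 23.4% of 638 regions in replicate 1 (24.8%, adjusted exact p = 0.0070) and 22.4% of 1032 in replicate 2 (30.9%, 9.2e-19). It had the direction of H3K36me3 at 16.3% of 459 regions in replicate 1 (22.8%, adjusted exact p = 3.0e-08) and 12.7% of 1611 in replicate 3 (17.2%, 1.5e-21). All 4 shares lay below those of unassociated lists, which were low already. The exact tests take regions as independent, which those on one scaffold are not, and 1 region per scaffold was not tried here. A comparison with the regions listed in both replicates of the other mark was chosen after seeing the data. H3K9ac replicate 2 had the same direction at 33.5% of 224 H3K4me3 regions (33.8% unassociated, adjusted exact p = 1) and 15.5% of 291 H3K36me3 regions (15.7%, adjusted exact p = 0.569). It was higher at 148 and lower at 74 of the falling H3K4me3 regions, and higher at 245 and lower at 42 of the falling H3K36me3 regions. Few of these methylation regions rose, which keeps the shares close to those of unassociated lists. For H3K4me3 the smallest unadjusted exact p its table allows was 0.111, so that test could not pass. With H3K27ac the share with the same direction was 96.5% of 991 regions (60.2%, adjusted exact p = 1.7e-198). Against single H3K27ac replicates it was 80.6% of 1779 regions in replicate 1 (55.2%) and 90.8% of 2405 in replicate 2 (50.4%). H3K27ac replicate 2 stood between these values, with 56.3% of 1436 regions in the direction of H3K36me3 replicate 3 (53.8%) and 69.9% of 1369 in that of H3K4me3 replicate 2 (62.6%). H3K4me3 and H3K36me3 had the same direction at 97.9% to 99.6% of regions whichever replicates were compared (72.6% to 92.3% unassociated).

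**Figure D3:**
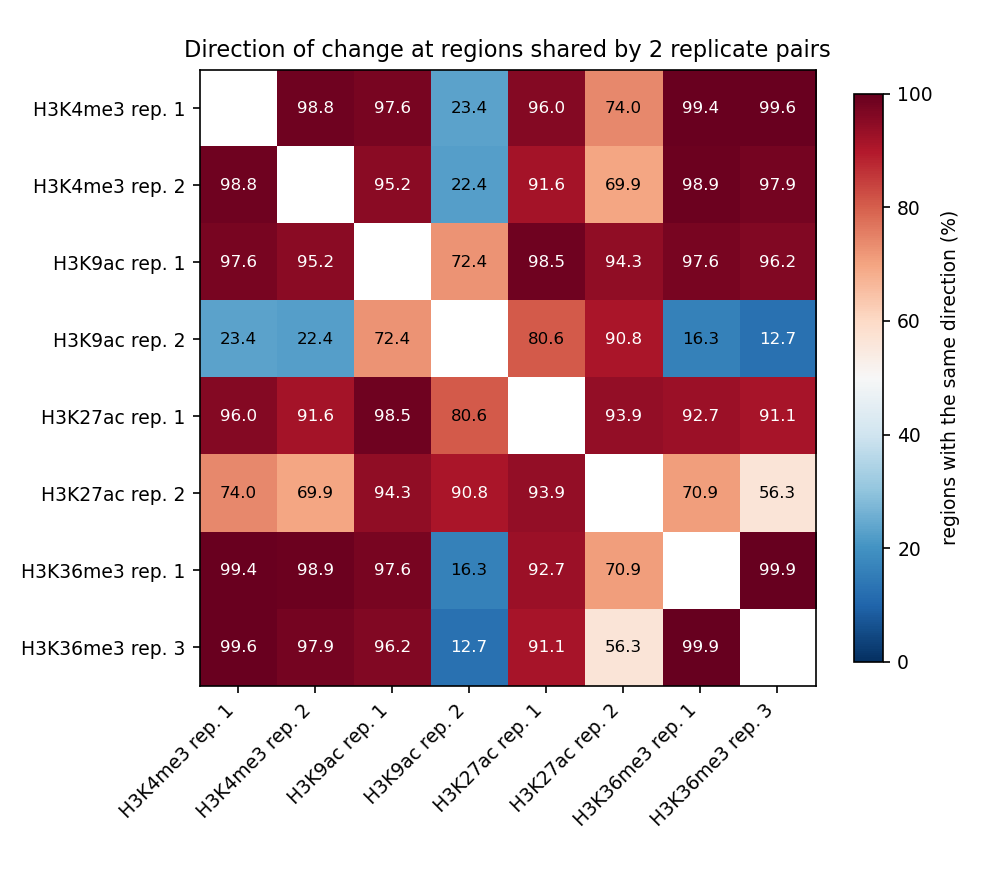
Each cell gives the percentage of regions listed in both of 2 replicate pairs (x and y axes, mark and replicate) that changed in the same direction, from 0 (blue) to 100 (red). The 4 cells that pair H3K9ac replicate 2 with a methylation mark lie between 12.7% and 23.4%, and those that pair H3K9ac replicate 1 with one lie between 95.2% and 97.6%.

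Regions of all marks that overlapped were joined into 8607 loci. Of these, 7598 were lower and 977 higher at 7PM, and 32 held both directions; 1432 were changed in more than 1 mark. The most frequent combinations were lower H3K9ac with lower H3K27ac (540 loci), lower H3K4me3 with lower H3K36me3 (430) and higher H3K9ac with higher H3K27ac (132). At 22 loci all 4 marks were lower in both replicates. The 5 with the largest mean change were on Peaxi162Scf00316 at 487001 to 492000, Peaxi162Scf00604 at 239001 to 243600, Peaxi162Scf00525 at 862601 to 866000, Peaxi162Scf00332 at 238201 to 241800 and Peaxi162Scf00039 at 841801 to 849800. On Peaxi162Scf00316 the log2 folds were −1.56 ± 0.067 for H3K4me3, −2.65 ± 0.75 for H3K9ac, −3.07 ± 0.041 for H3K27ac and −1.13 ± 0.17 for H3K36me3 (SD, n = 2 replicate pairs). No locus was higher in all 4 marks. One was higher in 3, on Peaxi162Scf01060 at 128001 to 131200, with log2 folds of 1.07 ± 0.029 for H3K4me3, 2.42 ± 0.45 for H3K9ac and 1.71 ± 0.81 for H3K27ac. The next by rank were listed higher in both acetylation marks: Peaxi162Scf00002 at 345401 to 351400, Peaxi162Scf00655 at 132601 to 134600, Peaxi162Scf00825 at 229201 to 230600, where H3K27ac had a log2 fold of 2.99 ± 0.34, and Peaxi162Scf00314 at 862801 to 865800, where H3K9ac had one of 2.55 ± 0.067.

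**Figure D4:**
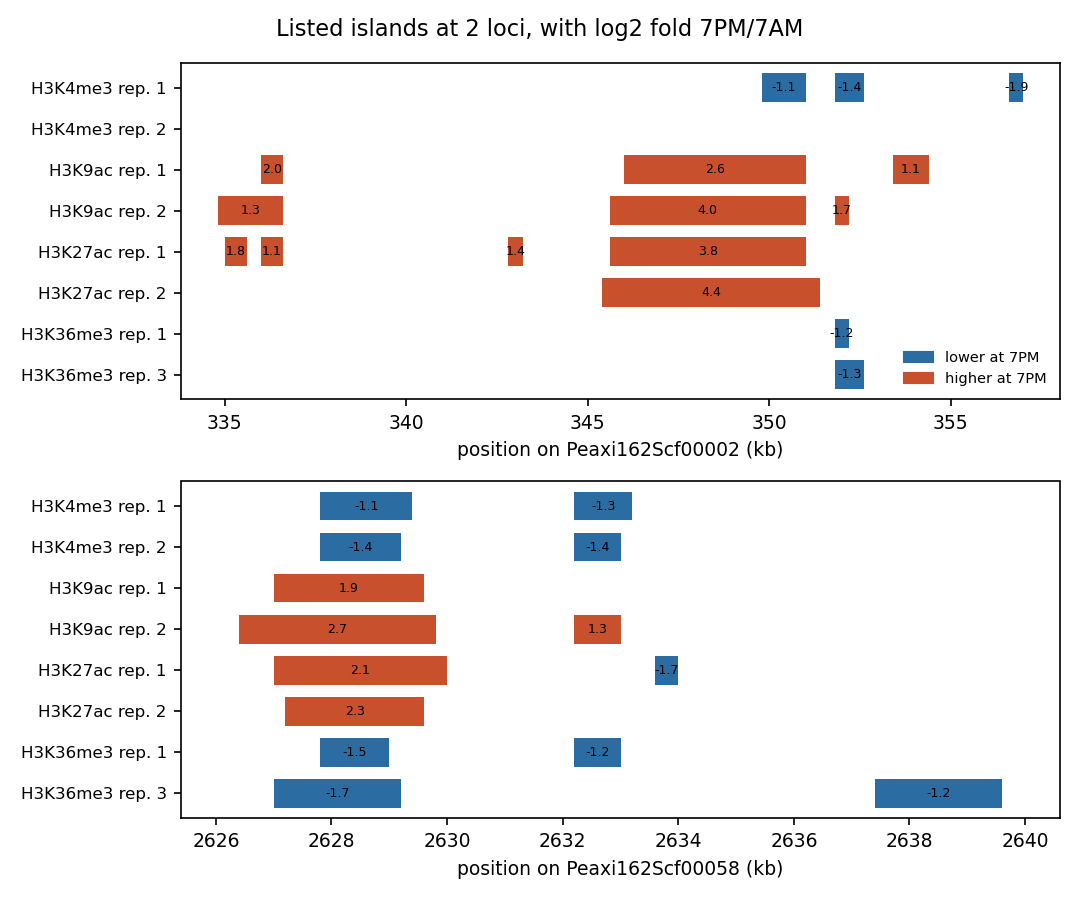
Islands in each deposited list along Peaxi162Scf00002 (top) and Peaxi162Scf00058 (bottom), with position in kb on the x axis, a track per mark and replicate, blue for lower and orange for higher at 7PM, and the log2 fold of each island printed on it. On Peaxi162Scf00002 both acetylation marks are higher over 345401 to 351400 with log2 folds of 2.64 to 4.36, and on Peaxi162Scf00058 acetylation is higher over 2626401 to 2630000 where the methylation marks are lower.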

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

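In this section, the tests of explanations that concern H3K9ac replicate 2, sequencing depth and island borders were chosen after the results were seen. The agreement of 72.4% between the H3K9ac replicates, which one of them uses, came from a planned comparison. The tests of read density per mark were chosen before, and their comparison with single replicates was chosen after.

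At a small number of places, 2 marks had opposite directions although each had one direction in both of its replicates. This held for 12 regions of H3K4me3 and H3K9ac, 9 of H3K4me3 and H3K27ac, 12 of H3K9ac and H3K36me3 and 13 of H3K27ac and H3K36me3, with acetylation higher and methylation lower in each, and for 1 region of H3K9ac and H3K27ac. The difference between marks was not tested at these places. At 3 loci all 4 marks took part: Peaxi162Scf00013 at 795201 to 797000, Peaxi162Scf00058 at 2626401 to 2630000 and Peaxi162Scf00286 at 431601 to 438800, chosen after their values were seen. On Peaxi162Scf00058 the log2 folds were 2.33 ± 0.59 for H3K9ac and 2.19 ± 0.096 for H3K27ac, against −1.27 ± 0.20 for H3K4me3 and −1.58 ± 0.11 for H3K36me3 (SD, n = 2 replicate pairs). The 1 region with opposite acetylation marks was on Peaxi162Scf00912 at 217601 to 225200, with 1.53 ± 0.58 for H3K9ac and −1.15 ± 0.042 for H3K27ac, and was also chosen after its values were seen.

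H3K9ac replicate 2 was mostly higher at 7PM where H3K4me3 and H3K36me3 were lower. An exchange of its 7AM and 7PM labels would put most of the regions it shares with H3K9ac replicate 1 in opposite directions, but 72.4% (95% interval 70.6 to 74.2) had the same one, which argues against it. A real opposition of H3K9ac and methylation would make replicate 1 higher there too. Of the 278 of 2180 such places that it lists in one direction, 40.6% were higher (34.8 to 46.7), much as the 41.1% of all places where replicate 2 rose. Of all islands of replicate 1, 79.2% were lower, so a share below an even split does not decide on a real opposition. The 1896 places that replicate 1 does not list are undecided as well. Stronger enrichment of the 7PM library of replicate 2 than of its 7AM library would make rising islands denser in reads than falling ones. A rising island was denser with a probability of 0.657 (interval over resampled scaffolds 0.647 to 0.667), so unequal enrichment of these libraries remains a candidate explanation, and a real difference between the 2 biological replicates was not tested. H3K27ac replicate 2 was also higher where H3K36me3 replicate 3 was lower at 596 of 1436 shared regions, against 124 of 1624 for H3K27ac replicate 1. The pattern was thus not confined to H3K9ac, and whether both acetylation marks share a cause was not tested.

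Regions that fell outnumbered those that rose for every mark; unequal depth would turn the balance with the deeper library, but falling regions made up 77.0% for H3K9ac and 89.6% for H3K27ac, whose 7PM libraries were the deeper ones, and 94.3% for H3K36me3, whose 7AM libraries were, which argues against depth as the whole cause. Weaker enrichment at 7PM may lower all strong regions alike and leave rises to weak ones, and rising regions were denser than falling ones with a probability of 0.0663 for H3K4me3 (0.047 to 0.091; 0.028 and 0.213 with the reads of replicates 1 and 2 apart) and 0.227 for H3K36me3 (0.182 to 0.273; 0.136 and 0.362 for replicates 1 and 3), so it stays open for these 2 marks, beside a real loss by evening. For H3K9ac the probability was 0.611 (0.580 to 0.642), with 0.530 (0.498 to 0.562) and 0.689 for replicates 1 and 2. The joint value goes against weaker enrichment, but it rests on replicate 2, whose 7PM library may be the more enriched one. The interval of replicate 1 includes an even chance, so the probability does not decide on weaker enrichment for this mark. For H3K27ac it was 0.496 (0.466 to 0.525; 0.422 and 0.564), where weaker enrichment and a real loss cannot be told apart because the replicates lie on opposite sides of an even chance. Whole lists of single replicates, which hold more than these regions, gave 0.044 and 0.509 for H3K4me3, 0.219 and 0.145 for H3K36me3, 0.474 and 0.657 for H3K9ac and 0.361 and 0.513 for H3K27ac.

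Falling islands of H3K4me3 and H3K36me3 overlapped with nearly the same borders, although these marks usually occupy the start and the body of a gene. Between H3K4me3 replicate 1 and H3K36me3 replicate 1 the median shared fraction (length in both over length in either) was 0.812 (0.80 to 0.833; 1342 overlapping pairs), as high as the 0.818 (0.80 to 0.833) between the replicates of H3K4me3, whereas H3K4me3 replicate 1 and H3K27ac replicate 1 gave 0.459. The replicates of H3K27ac gave only 0.625 (0.60 to 0.636) between themselves, so a contrast with this mark is of limited use. Chromatin of one replicate number divided between antibodies does not account for the common borders of H3K4me3 and H3K36me3 as a whole, since H3K4me3 replicate 1 and H3K36me3 replicate 3 gave 0.80 (0.778 to 0.80). A signal common to both antibodies, such as background chromatin, could give such borders, and the input samples, not used here, would bear on it. Both marks lying over the same short domains stays open too, and H3K4me3 replicate 2 with H3K36me3 replicate 3 gave a lower value, 0.571.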

How the results depend on the processing

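Counts of listed or called places changed most. Named regions and loci were chosen for one direction in both replicates, so leaving a replicate out does not test their direction. Among values of the 40 named regions under settings that could change a call, 193 of 241 kept their side of the threshold. Without the block 9 of the 10 H3K4me3 regions no longer passed, and 39 H3K9ac values passed where they had not before. Of these H3K9ac values, 10 came with TMM, 9 with median-of-ratios scaling, 10 with DESeq2 and 10 with the filter of 50 reads. Both scalings move every fold upwards, so they do not test the H3K9ac rises. All named regions met the filter by the rule that chose them. Agreement between replicates stayed past the threshold in its direction in all 16 alternative values apart from those with a fold of 1.5. A fold of 1.5 removed no island, since all exceed 2.00-fold, so it tests nothing. Leaving out single libraries leaves no residual degrees of freedom with the block, and this and the gene lists were not run. The filter of 50 reads for agreement, H3K9ac single replicates against both replicates of another mark, and loci without H3K9ac were chosen after seeing the data. Where no cause is given below, the cause was not tested; stricter filters keep fewer islands by construction. At under 50 reads, 91.8% of H3K27ac and 67.5% of H3K9ac regions had the same direction in both replicates, against 99.9% and 87.6% at or above it. At under 50 reads the shares for H3K4me3 and H3K36me3 were 96.1% and 99.3%, above that of H3K9ac at or above 50 reads. Unassociated lists would share 53.8% for H3K9ac at or above 50 reads, and no such share was computed for regions under 50 reads. The comparison across marks therefore does not decide whether read number accounts for the disagreement of the H3K9ac replicates. At or above 50 reads, 74 of 598 H3K9ac regions still had opposite directions.

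With an FDR of 1e-05 the lists of H3K27ac held 8357 lower and 1588 higher islands in replicate 1 (13115 and 3227 before) and 5666 and 2025 in replicate 2 (11997 and 4977), those of H3K9ac 2786 higher in replicate 1 (5699) and 1746 lower in replicate 2 (5331), and that of H3K36me3 replicate 3 held 3433 higher (5880). With at least 50 reads they held 4882 and 608 for H3K27ac replicate 1, 1649 and 668 for replicate 2, 8318 (21714 before) and 925 for H3K9ac replicate 1, 496 lower and 3338 higher (6415) for replicate 2, 1697 higher (3277) for H3K4me3 replicate 1, 6252 lower (9569) and 3277 higher (9669) for replicate 2, and 2175 (4021) and 1142 higher for H3K36me3 replicates 1 and 3. The share lower at 7PM crossed an even split in H3K36me3 replicate 1 (47.9% before, 50.8% with the stricter FDR, 58.5% with 50 reads) and H3K4me3 replicate 2 (49.7%, then 57.3% and 65.6%).

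Regions listed in one direction in both replicates numbered, with the stricter FDR, 118 higher for H3K4me3 (186 before), 606 lower and 256 higher for H3K9ac (1352 and 404), 2090 and 257 for H3K27ac (3680 and 425) and 79 higher for H3K36me3 (146). With 50 reads they were 49 higher for H3K4me3, 352 and 172 for H3K9ac, 1015 and 141 for H3K27ac and 31 higher for H3K36me3. With 50% reciprocal overlap they were 101 higher for H3K4me3 and 862 lower for H3K9ac. Without either replicate, the other list alone gave 5143 to 9569 lower and 3277 to 9669 higher for H3K4me3, 5331 to 21714 and 5699 to 6415 for H3K9ac, 11997 to 13115 and 3227 to 4977 for H3K27ac, and 3702 to 11648 and 4021 to 5880 for H3K36me3, since a single list needs no second one.

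In the count test, TMM gave 18 lower for H3K4me3 (1656 before), 54 lower and 345 higher for H3K9ac (0 and 0), 66 lower for H3K27ac (3638) and 81 lower for H3K36me3 (2418), and median-of-ratios scaling 15, 27 and 359, 64, and 57. The share lower among calls fell from 89.9% to 8.82% and 7.46% for H3K4me3, from 89.7% to 13.6% and 13.3% for H3K27ac and from 94.3% to 34.3% and 27.5% for H3K36me3. Both scalings centre the tested regions near no change and move every fold upwards. Most tested regions fell, so the loss of most lower calls follows from the centring and tests neither falls nor rises as a group. A fall that still passed was larger than that of most tested regions. Whether most tested regions changed relative to unlisted chromatin was not tested. For H3K9ac, DESeq2 with the block gave 408 lower and 156 higher, and 50 reads gave 316 and 155. With 50 reads the test called 1015 lower and 141 higher for H3K27ac, 49 higher for H3K4me3 and 31 higher for H3K36me3; with the stricter FDR 2091 and 257 for H3K27ac, 118 higher for H3K4me3 and 79 higher for H3K36me3; with reciprocal overlap 101 higher for H3K4me3. Without the replicate block edgeR called 16 lower and 0 higher for H3K4me3 (467 and 44 at an unadjusted p under 0.05, and 1617 and 141 by DESeq2 with the block), and its counts for H3K27ac, H3K36me3 and H3K9ac stayed within 1.5 times of those with it. Samples with the same number deviated together (correlations across regions 0.80, 0.48, 0.52 and 0.85 for H3K4me3, H3K9ac, H3K27ac and H3K36me3), which island borders set per pair also produce.

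Between marks, regions listed in both replicates gave tables that could not pass, apart from H3K9ac with H3K27ac, and single replicates passed for H3K4me3 and H3K9ac (97.6% with replicate 1 of both, 95.2% with H3K4me3 replicate 2 and H3K9ac replicate 1), H3K4me3 and H3K27ac (96.0%, 91.6% and 69.9%), H3K4me3 and H3K36me3 (99.4%, 99.6%, 98.9% and 97.9%), H3K9ac and H3K36me3 (97.6% and 96.2% with H3K9ac replicate 1) and H3K27ac and H3K36me3 (92.7%, 91.1%, 70.9% and 56.3%), where more regions are compared. H3K9ac replicate 1 alone gave 98.1% with H3K4me3 and 98.3% with H3K36me3 (97.6% and 95.7% for unassociated lists). With H3K9ac replicate 2 fewer regions had the same direction than unassociated lists would give: 23.4% and 22.4% with H3K4me3 (24.8% and 30.9% unassociated; adjusted exact p = 0.0070 and 9.2e-19) and 16.3% and 12.7% with H3K36me3 (22.8% and 17.2%; 3.0e-08 and 1.5e-21), so these 4 passed in the opposite direction. Against regions listed in both replicates of these marks the shares were 33.5% and 15.5%, close to 33.8% and 15.7% for unassociated lists (adjusted exact p = 1 and 0.569). Few of these methylation regions rose, which keeps the 2 kinds of share close, and the table with H3K4me3 could not pass. The exact tests between marks take regions as independent, which those on one scaffold are not. Without H3K9ac 20 loci held both directions, in place of 32.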

Other observations

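The tests of neighbouring regions were chosen before their results were seen. Regions of one mark that lay within 10 kb of each other on a scaffold mostly had one direction. This held for 86 of 88 neighbouring pairs of H3K4me3 (97.7%), 147 of 154 of H3K9ac (95.5%), 529 of 547 of H3K27ac (96.7%) and 175 of 176 of H3K36me3 (99.4%). Shuffling the directions among the regions of a mark 10000 times gave means of 81.8%, 64.6%, 81.4% and 89.2%, and no shuffle reached the observed share for any of the 4 marks (permutation p = 0.0001 each, the smallest these shuffles can give, and 0.0001 after Benjamini-Hochberg adjustment). Higher neighbours were most frequent in H3K9ac, with 25 pairs, against 15 in H3K27ac, 1 in H3K4me3 and 0 in H3K36me3. Changes that extend over more than one called region are a candidate explanation, and the splitting of one domain into several islands by the authors' calling could give the same values and was not tested.

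Lower H3K4me3 and lower H3K36me3 overlapped in 509 pairs of regions listed in both replicates. H3K36me3 reached beyond H3K4me3 on one side only in 199 of them, on both sides in 42 and on neither side in 268, and the median lengths were 2200 bp for H3K4me3 and 2400 bp for H3K36me3. Identical start and end positions were found for 27.4% of the overlapping falling islands of H3K4me3 replicate 1 and H3K36me3 replicate 1, for 20.4% of those of replicates 1 and 3, 20.3% of those of replicates 2 and 1 and 9.81% of those of replicates 2 and 3, for 28.9% between the replicates of H3K4me3, and for 7.93% of those of H3K4me3 replicate 1 and H3K27ac replicate 1. Between the replicates of H3K27ac the share was 7.6%, so the value of 7.93% is no lower than that of H3K27ac with itself.

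The rise of H3K27ac on Peaxi162Scf00002 took up a stretch of 6000 bp, and the lists held lower H3K36me3 beside it. An island from 351801 was lower for H3K36me3 in both replicates, with 29 reads at 7AM and 11 at 7PM in replicate 1 and 34 and 11 in replicate 3. H3K4me3 replicate 1 was lower there as well, with 65 and 36 reads. It was also lower within the rise, at 349801 to 351000, with 85 and 57 reads. H3K9ac replicate 2 was higher at 351801 to 352200, with 5 reads at 7AM and 22 at 7PM. H3K4me3 replicate 2 had no listed island in the mapped stretch. This place was chosen after its values were seen.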
